A study of Sus scrofa with 37 samples.

How the data were processed

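The study covers single-cell RNA libraries of pig bone marrow, thymus and fetal liver. Per the labels' protocols, thymus was digested with collagenase at 37 °C for 30 minutes, liver was homogenised, lysed for red cells and sorted on CD45, and all suspensions were sorted for live cells with propidium iodide. Marrow came from scapula and limb bones at 47 DG, femur and tibia at 60, 75 and 90 DG, and ribs and sternum at 1 DOA and 7 MOA. Titles call the first marrow age day 45 where the design text says 47 DG, and the design text once gives 70 DG where samples were taken at 75 DG; 47 and 75 DG are used here. Replicate numbers are 1, 2 and 4 at 47 DG. V(D)J libraries named in the protocol were not analysed here.

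The deposited matrices hold raw UMI counts per gene and cell made by the authors with Cell Ranger 8.0.0 from 10x 5-prime v2 libraries, per the submitters' processing notes and the file headers. The genome build and annotation are not given in the sources used here. Marrow and thymus files share 22040 genes and liver files hold another list, so liver was not tested against other tissues. IGF2 and HBE1 are absent from the 22040 gene names.

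Cells with at least 500 UMIs, at least 200 genes and at most 15% mitochondrial UMIs were kept (27.1% to 97.6% of barcodes per marrow library, 98.2% to 99.8% in thymus, 91.3% to 96.8% in liver). Doublets were called per library with the scrublet function of scanpy 1.11.5 and left out, but this marked only 592 cells (0.284%), so an alternative removed the highest scores at 0.8% per 1000 cells. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes gave 30 principal components and 15 neighbours, and Leiden clustering (python-igraph 0.11.9) was run per tissue at resolution 1, without batch integration. Clusters were named from 23 marker lists when at least 3 markers were 1.5-fold raised at 20 CPM or more and the score was at least 0.5, jointly when 2 scores lay within 0.2; "-like" marks such names. Other tools were Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scikit-image 0.26.0, matplotlib 3.10.9 and R 4.3.3.

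For each class, counts were summed per library with at least 30 cells, filtered with filterByExpr, scaled by TMM and fitted by age group with the robust quasi-likelihood test of edgeR 4.0.16. Comparisons were postnatal against prenatal, 7 MOA against 1 DOA and 90 DG against 60 DG, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The first uses differences of means of age-group coefficients, so its fold changes need not equal the ratio of mean CPMs. Shares of cells were compared by exact permutation of libraries, adjusted over the classes of a tissue; 3 against 3 libraries cannot give a p under 0.1, so single ages are given as means. Gene lists (14, fixed, with class markers left out) were tested with camera in limma 3.58.1 at a correlation of 0.01 on log2 CPM with a prior count of 2, adjusted over all 124 tests. On simulated data with 200 changed genes, 4-fold changes were found in 63% to 98% and 2-fold changes in 13% to 86%, the 3 lowest in the 90 DG against 60 DG fits of marrow. Unchanged genes made up 1.06% to 13.5% of the genes called there, above the 5% of the threshold in HSPC-like cells (8.98% after birth, 13.5% from 1 DOA to 7 MOA) and other fits.

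Named genes followed a rule: up to 4 largest rises and falls (3 for 90 DG against 60 DG) among genes with an absolute log2 fold change over 1, libraries that do not overlap and 50 CPM or more, up to 4 members with the smallest p of each list that passed or had 3 changed members, and LIN28B, IGF2BP3, DNTT, RAG1, HBZ and HBM always. Left out were class markers, XIST, mitochondrial, ribosomal, unnamed and receptor segment genes, haemoglobins outside erythroid cells and genes under 10% of another class's level. For length, the text prints the first 4, 3 and 2 per direction in the 3 comparisons and 1 or 2 list members in order of p, whatever their stability. Some genes that this rule selects are not reported here.

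Alternatives were size factors of the RLE kind, DESeq2 1.42.0, no expression filter, the replicate number as a block, at least 100 cells per library, at least 500 genes per cell, doublets kept, Leiden resolution 2, each library left out, no 47 DG libraries, shares of non-erythroid cells and an estimated camera correlation. Groups, tests, lists, the named-gene rule and these alternatives were set before the data were examined. Doublets by rate, no 60 DG libraries, low-gene barcodes counted as erythroid, thymocyte-like cells left out, and leaving unnamed clusters out of the share tests were chosen afterwards. That last choice moved no call. Of 666 library pairs, none shared over 2.91% of barcodes.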

Results

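Single cells of pig haematopoietic tissue were profiled with droplet RNA sequencing in 37 libraries, 18 from bone marrow, 15 from thymus and 4 from fetal liver. Bone marrow was sampled at 47, 60, 75 and 90 days of gestation (DG), at 1 day of age (DOA) and at 7 months of age (MOA), thymus at 60, 75 and 90 DG, 1 DOA and 7 MOA, each with 3 libraries, and liver at 41 DG. The files held 99119 marrow, 92584 thymus and 39023 liver barcodes, of which 79116, 91956 and 36854 were kept as single cells. Total UMIs per library were 5820820 to 94606340 in marrow, 13812446 to 72424245 in thymus and 193150841 to 225727857 in liver. Median UMIs per kept cell ran from 2023 to 14952 over the marrow libraries, from 2074 to 4346 in thymus and from 7708 to 10308.5 in liver. Values in brackets after a gene are edgeR log2 fold changes, later over earlier age, with an SE derived from the F test after ±. Elsewhere ± gives SD. The postnatal side pools 1 DOA and 7 MOA, so a change after birth need not hold at both. The largest rises and falls named are those among genes at 50 CPM or more whose libraries do not overlap. Stress genes stand for the immediate early and heat shock list, and where a list has no second count, as many genes passed when adjusted over the list alone. Tests take libraries, not ages, as replicates. No label says they came from separate animals, so p-values measure only spread between libraries, which may be technical.

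The first question was how the marrow's cell makeup changes. Erythroid-like cells made up 2.91% ± 1.23 of kept cells at 47 DG, 33.2% ± 8.05 at 60 DG, 54.9% ± 0.684 at 75 DG and 74.6% ± 7.07 at 90 DG, then 28.0% ± 12.2 at 1 DOA and 18.1% ± 13.5 at 7 MOA (n = 3 libraries at each age). Neutrophil-lineage-like cells ran from 62.8% ± 4.92 at 47 DG to 11.2% ± 2.84 at 90 DG and stood at 46.1% ± 9.68 at 1 DOA and 66.8% ± 12.8 at 7 MOA. Monocyte- and macrophage-like cells, a class also called monocyte-like below, were 18.7% ± 5.0001 at 47 DG and 1.33% to 6.51% at the later ages. B-precursor-like cells were 13.5% ± 4.37 at 60 DG, 7.30% ± 2.43 at 1 DOA and 0.0213% ± 0.0208 at 7 MOA. Natural killer or other cytotoxic (NK-like) cells were 0.221% to 0.309% before birth, 0.667% ± 0.205 at 1 DOA and 5.96% ± 1.12 at 7 MOA. Haematopoietic stem and progenitor (HSPC)-like cells were 0.4998% to 1.32% at every age.

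In the postnatal against prenatal test (6 against 12 libraries, 2-sided exact permutation), NK-like cells were higher after birth (mean 3.31% against 0.283%, adjusted p = 0.000593), and no other marrow class that reached a mean of 1% at some age, the floor for testing, passed, with erythroid-like cells at adjusted p = 0.386. Without the 47 DG libraries, erythroid-like cells passed (difference -31.2 points, adjusted p = 0.00967), as did neutrophil-lineage-like (37.1, adjusted p = 0.0011), monocyte- and macrophage-like (3.31, adjusted p = 0.00513) and B-precursor-like cells (-7.63, adjusted p = 0.00967). Neutrophil-lineage-like cells also passed without 47 DG replicate 1 (29.4, adjusted p = 0.036) or 4 (29.5, adjusted p = 0.0231) and with finer clusters (22.4, adjusted p = 0.011), after adjusted p = 0.064 with all libraries. The adjusted p of B-precursor-like cells was 0.0616 with all libraries. They passed with finer clusters (-6.21, adjusted p = 0.046), without thymocyte-like cells in the denominator (-6.71, adjusted p = 0.049), and without 47 DG replicate 1 (-6.66, adjusted p = 0.0483) or 4 (-7.32, adjusted p = 0.0107), 90 DG replicate 1 (-6.98, adjusted p = 0.0382) or 1 DOA replicate 2 (-7.61, adjusted p = 0.0249) or 3 (-7.36, adjusted p = 0.04). Prenatal bones (scapula, limb bones, femur, tibia) differ from postnatal ones (ribs, sternum), so birth and bone cannot be told apart. All samples were sorted for live cells.

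At 60 DG, 65.4% ± 9.13 of marrow barcodes held fewer than 200 genes, against 3.04% to 9.78% at the other ages, and 15045 of these 15058 barcodes had over 10% of their UMIs from HBB, the adult beta-globin. With such barcodes counted as erythroid, the erythroid-like share read 5.12%, 76.4% ± 9.16, 56.8% and 76.7% from 47 to 90 DG, 31.2% at 1 DOA and 19.1% at 7 MOA. HBB took 8.13% to 13.2% of the UMIs of neutrophil-lineage-like cells at 60 DG and 0.0309% to 1.55% at 90 DG. A cluster with markers of both B precursors and mature B cells held 16.3% ± 4.79 of the cells at 60 DG and 0.0222% to 0.535% at the other ages. In 60 DG replicate 3, 21.1% of the cells (1305) resembled double-positive (DP) thymocytes.

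**Figure D1:**
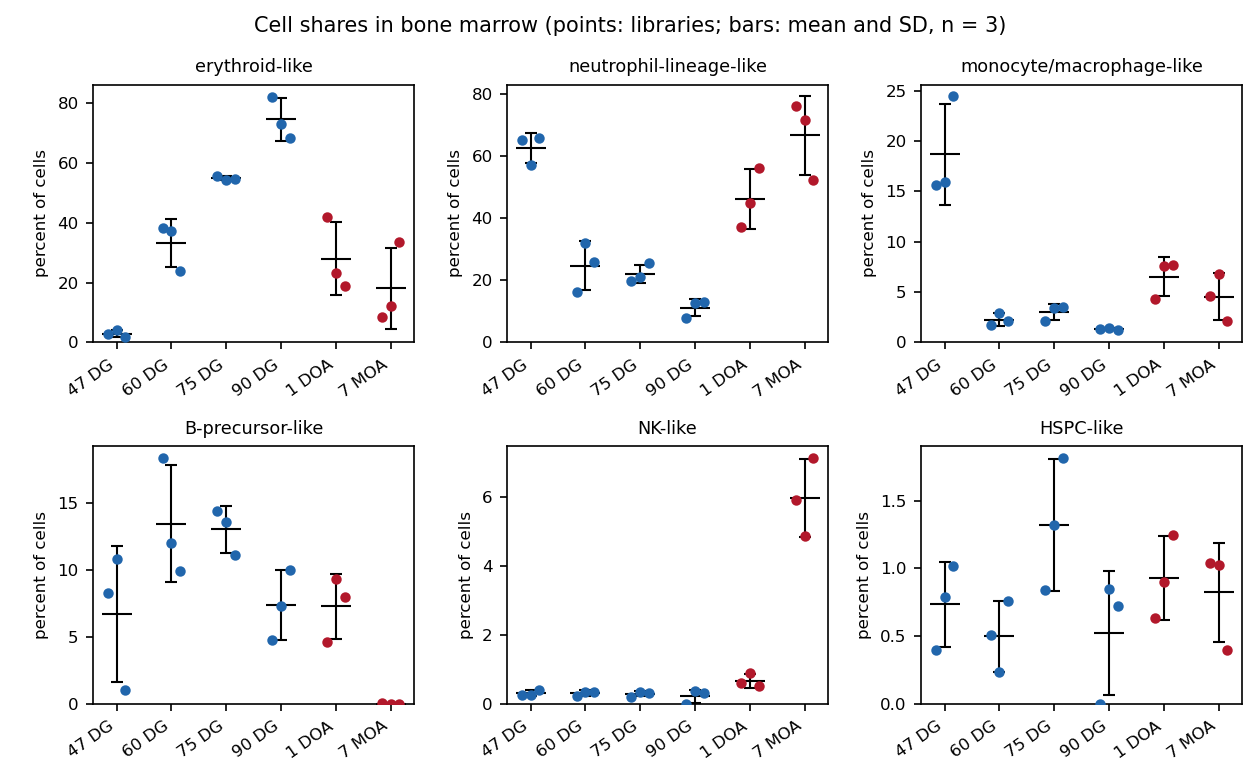
Percent of kept bone marrow cells (vertical axes) by age (horizontal axes) for 6 cell classes, with points for libraries, blue before and red after birth, and bars for mean and SD (n = 3). Erythroid-like cells reach 74.6% at 90 DG and NK-like cells 5.96% at 7 MOA.

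**Figure D2:**
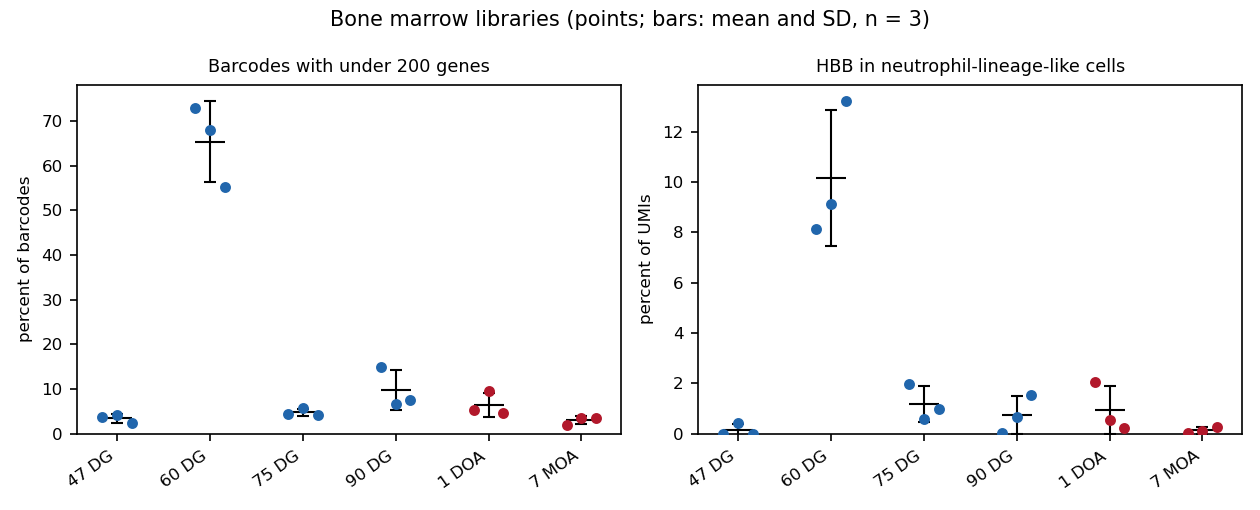
Percent of barcodes with fewer than 200 genes (left) and percent of UMIs from HBB in neutrophil-lineage-like cells (right) by age, with points for bone marrow libraries and bars for mean and SD (n = 3). The 60 DG libraries stand apart in both, with a mean of 65.4% on the left.

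In thymus, DP-thymocyte-like cells, the stage that rearranges T-cell receptor alpha genes, were 72.5% ± 0.934 at 60 DG and 38.0% to 44.9% at the later ages (n = 3 libraries each). Single-positive (SP) alpha-beta T-like cells were 8.62% ± 1.24 at 60 DG and 19.04% ± 5.69 at 1 DOA, double-negative-like cells 2.82% ± 0.440 at 60 DG and 9.15% ± 0.635 at 7 MOA, and gamma-delta T-like cells 1.70% ± 0.493 at 60 DG and 6.86% ± 2.43 at 7 MOA. Clusters left unnamed, led by proliferation genes, held 11.9% to 32.3% of the cells, so the cycling thymocytes lie largely outside the classes compared. After birth (6 against 9 libraries, 2-sided exact permutation), a cluster with DP and gamma-delta markers (4.38% against 0.667%), NK-like cells (2.51% against 0.751%) and plasma-like cells (1.32% against 0.437%) were higher, each with adjusted p = 0.000666, as were SP-like cells (17.4% against 11.7%, adjusted p = 0.0145). Monocyte-like cells were also higher (2.12% against 0.728%, adjusted p = 0.04), but missed the threshold at 500 genes per cell (difference 0.692 points, adjusted p = 0.271) and without any 1 of 12 of the 15 libraries (adjusted p 0.0506 to 0.0659). Double-negative-like and gamma-delta T-like shares did not pass.

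**Figure D3:**
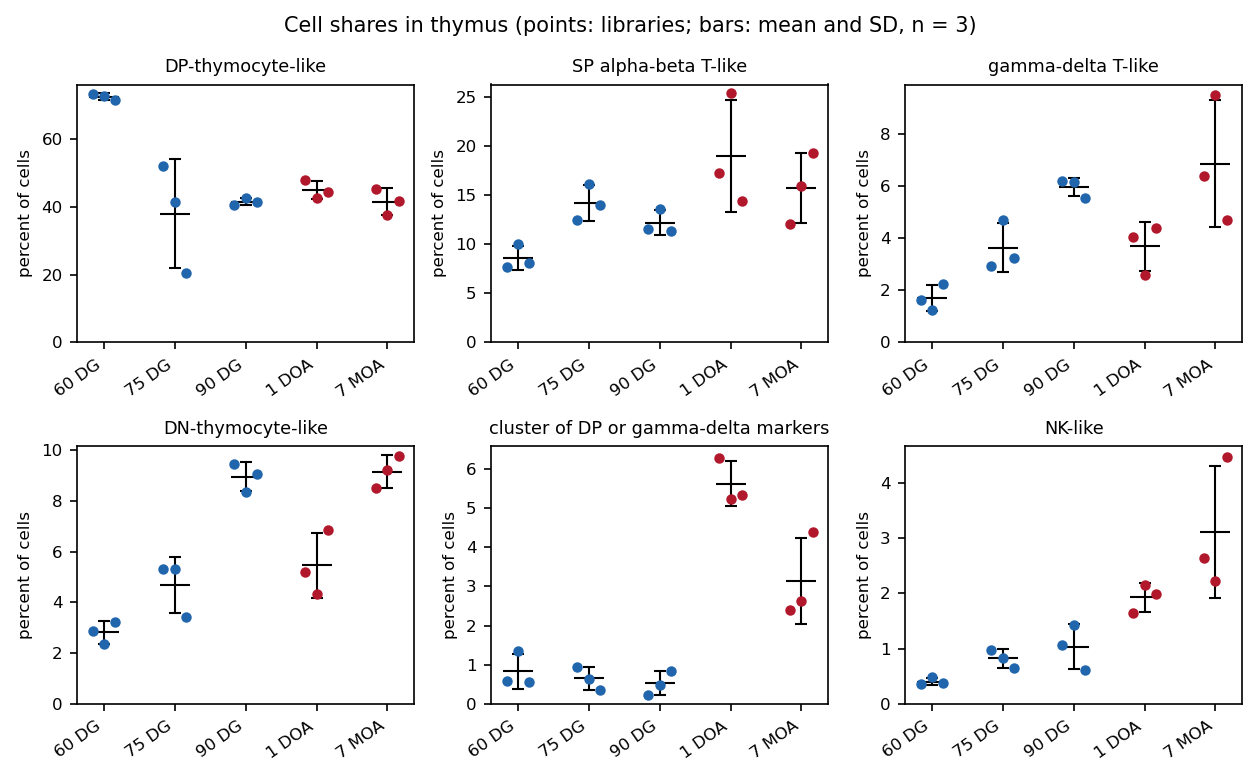
Percent of kept thymus cells (vertical axes) by age (horizontal axes) for 6 cell classes, with points for libraries, blue before and red after birth, and bars for mean and SD (n = 3). DP-thymocyte-like cells stand at 72.5% at 60 DG against 38.0% to 44.9% later.

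Fetal liver at 41 DG held 67.0% ± 8.04 erythroid-like, 13.8% ± 7.82 neutrophil-lineage-like, 7.71% ± 1.22 HSPC-like and 3.68% ± 1.06 monocyte-like cells (n = 4 libraries). Mast-cell-, basophil- or eosinophil-like cells made up 0.821%, megakaryocyte-like cells 0.690%, B-precursor-like cells 0.352% and unnamed cells 5.73%. With finer clusters monocyte-like cells were 0.749%, megakaryocyte-like cells 1.36% and unnamed cells 10.6%, and with doublets removed by rate B-precursor-like cells were 0.225%. Erythroid-like cells were 79.0% in replicate 1 (95% Wilson interval 78.0% to 79.9%, counting error only) and 62.3% to 64.1% in the others. The suspensions had been lysed for red cells and sorted on CD45, the pan-leukocyte surface marker, and which library held positive or negative cells is not given in the sources used here, so no test was made and these shares can reflect the sort. HSPC-like cells of the 41 DG liver and of the marrow (0.4998% to 1.32%) were therefore only set side by side.

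Next, genes were compared between prenatal and postnatal cells of a class. Among HSPC-like cells (5 postnatal against 5 prenatal libraries, cluster 7 at every age), 1966 genes rose and 954 fell after birth of 9793 tested. The largest rises were in CEBPE (4.54 ± 0.41, adjusted p = 1.50e-07, 64.2 ± 16.3 against 6.88 ± 5.22 CPM), PPP1R14B (3.43 ± 0.29), TMEM160 (3.42 ± 0.37) and MRPS12 (2.93 ± 0.35). Among the largest falls were HSPA6 (-3.69 ± 0.27, adjusted p = 7.04e-09, 5.31 ± 3.05 against 82.3 ± 63.0 CPM), an inducible heat shock protein, IGF2BP2 (-1.83 ± 0.12), an RNA-binding protein of the fetal programme, and MYO7A (-1.80 ± 0.23). 4 fetal programme genes fell, 1 rose and 5 did not pass (4 and 2 adjusted over the list alone, set adjusted p = 0.00829, or 0.221 with an estimated correlation), with IGF2BP1 (-4.14), LIN28B (-5.18), which blocks let-7 maturation, and IGF2BP3 (-0.74) down. At 1 DOA IGF2BP3 read 122 to 140.0 CPM, within the prenatal 59.2 to 176, and 25.5 to 46.2 at 7 MOA. LIN28B read 9.86, 14.6 and 23.2 at 1 DOA, against 22.3 to 28.2 at 75 and 90 DG, and 0 at 7 MOA. 15 cell cycle genes rose and 14 did not pass (17 adjusted over the list alone, set adjusted p = 9.31e-05, or 0.476 with an estimated correlation), including the mitotic regulators CDC20 (3.26) and PLK1 (3.15). 7 interferon genes rose and 9 did not pass (8 adjusted over the list alone, set adjusted p = 0.0279, or 0.371 with an estimated correlation), such as CMPK2 (2.99) and PARP14 (1.47). 9 MHC class I genes rose and 4 did not pass (10 adjusted over the list alone, set adjusted p = 0.00328, or 0.178 with an estimated correlation), led by CALR (0.95) and PSMB8 (0.82). 1 stress gene rose, 1 fell and 15 did not pass (set down at adjusted p = 0.0134, or 0.541 with an estimated correlation), with DNAJB1 (-0.56) down and HSPE1 (0.28) up. 4 stem cell identity genes fell, 1 rose and 12 did not pass (set adjusted p = 0.112), including falls of TXNIP (-0.92) and RUNX1 (-0.45). The glucocorticoid (1 up, 2 down, adjusted p = 0.605) and MHC class II (2 up, 1 down, adjusted p = 0.977) lists did not pass. The 47, 60 and 90 DG groups were 1 library each, replicates 2, 3 and 2, so the spread between libraries was not measured at these ages. Without the 60 DG library 1226 genes passed, against 1009 with DESeq2. CEBPE stood at 5.37 and 2.95 without 47 DG replicate 2 or 60 DG replicate 3. PPP1R14B stood at 0.95 and 4.49 without 60 DG replicate 3 or 90 DG replicate 2. TMEM160 stood at 1.51 and 4.41 without 60 DG replicate 3 or 90 DG replicate 2. MRPS12 stood at 0.74 to 3.68 without 47 DG replicate 2, 60 DG replicate 3 or 90 DG replicate 2. IGF2BP1 stood at -5.71 without 7 MOA replicate 2. IGF2BP3 lost its call without 60 DG replicate 3 (-0.53, adjusted p up to 0.0564). CDC20 stood at 1.04 and 4.06 without 60 DG replicate 3 or 90 DG replicate 2. PLK1 stood at 1.27 and 3.95 without 60 DG replicate 3 or 90 DG replicate 2. CMPK2 stood at 1.67 without 47 DG replicate 2. PARP14 lost its call with DESeq2 or with doublets removed by rate (1.45 and 0.97, adjusted p up to 0.127). DNAJB1 lost its call without 90 DG replicate 2 (-0.30, adjusted p up to 0.0652). HSPE1 lost its call with DESeq2 or without 60 DG replicate 3 or 7 MOA replicate 1 (0.14 to 0.26, adjusted p up to 0.366). RUNX1 lost its call without 60 DG replicate 3 (-0.10, adjusted p up to 0.561).

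Between 1 DOA and 7 MOA, from the same bones, HSPC-like cells (2 libraries at 7 MOA, 3 at 1 DOA) had 381 genes that rose and 301 that fell. The largest rises were in JUN (4.25 ± 0.53, adjusted p = 0.0228, 492 ± 224 against 26.1 ± 11.5 CPM) and DUSP1 (2.88 ± 0.33), immediate early genes, and CD69 (2.79 ± 0.49). The largest falls were in BUB1 (-1.98 ± 0.29, adjusted p = 1.72e-04), which acts in mitosis, ROR2 (-1.97 ± 0.28), a Wnt5a receptor, and IGF2BP3 (-1.88 ± 0.24). 16 cell cycle genes fell and 13 did not pass (23 adjusted over the list alone, set adjusted p = 2.13e-11, or 0.259 with an estimated correlation), led by CENPF (-1.68) and TOP2A (-1.58). 5 MHC class II genes rose and 3 did not pass (6 and 1 adjusted over the list alone, set adjusted p = 6.41e-04, or 0.333 with an estimated correlation), led by CD74 (2.02 ± 0.16, 2021 ± 242 against 498 ± 109.6 CPM), the invariant chain, and SLA-DQB1 (1.66). 9 stress genes rose, 2 fell and 6 did not pass (12 and 4 adjusted over the list alone, set adjusted p = 3.25e-04, or 0.440 with an estimated correlation), with BTG2 (2.43) besides DUSP1. 5 MHC class I genes rose, 2 fell and 6 did not pass (7 and 2 adjusted over the list alone, set adjusted p = 0.00486, or 0.180 with an estimated correlation), with PSMB9 (1.07) and B2M (1.25) up. 5 fetal programme genes fell, 1 rose and 4 did not pass (7 and 2 adjusted over the list alone, set adjusted p = 3.25e-04, or 0.166 with an estimated correlation), led by IGF2BP2 (-1.52) and with LIN28B (0 ± 0 against 15.9 ± 6.78 CPM) lower. 4 interferon genes rose and 12 did not pass (9 adjusted over the list alone, set adjusted p = 2.71e-05, or 0.178 with an estimated correlation), such as IRF7 (1.79) and IFI44L (1.11). 3 stem cell identity genes rose and 14 did not pass (4 adjusted over the list alone, set adjusted p = 0.0223, or 0.238 with an estimated correlation), led by MSI2 (0.82) and LMO2 (0.67). 2 glucocorticoid genes fell and 9 did not pass (set adjusted p = 0.0353, or 0.283 with an estimated correlation), FKBP5 (-0.91) and NR3C1 (-0.63). With DESeq2, 163 genes passed. JUN lost its call without 1 DOA replicates 2 and 3 (4.25 and 3.94, adjusted p up to 0.0884). CD69 lost its call without 1 DOA replicates 1 and 2 (3.03 and 2.92, adjusted p up to 0.109). B2M lost its call with DESeq2 (1.27, adjusted p up to 0.380). IRF7 lost its call with DESeq2 (1.87, adjusted p up to 0.498) and stood at 2.53 without 1 DOA replicate 3. IFI44L lost its call with DESeq2 or without 1 DOA replicates 1 and 3 (0.98 to 1.11, adjusted p up to 0.863). LMO2 lost its call with DESeq2 or without 1 DOA replicates 2 and 3 (0.60 to 0.69, adjusted p up to 0.889). FKBP5 lost its call with DESeq2 (-0.90, adjusted p up to 0.180). NR3C1 lost its call with DESeq2 (-0.61, adjusted p up to 0.645).

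Erythroid-like cells (6 postnatal against 10 prenatal libraries) had 2180 genes that rose and 990 that fell after birth of 13220. HERC6 (5.94 ± 0.72), an interferon-induced ligase, CA1 (4.198 ± 0.27, adjusted p = 8.03e-08, 1302 ± 1436 against 24.5 ± 10.3 CPM), carbonic anhydrase 1, NFIA (2.52 ± 0.16), a transcription factor that favours the erythroid fate, and SPN (1.80 ± 0.16), the sialophorin CD43, rose most. SLC2A1 (-7.27 ± 0.58, adjusted p = 1.99e-06, 0.815 ± 0.973 against 145 ± 88.3 CPM), the glucose transporter GLUT1, TTLL11 (-2.28 ± 0.29) and LDHA (-2.16 ± 0.22), lactate dehydrogenase A, were among those that fell most. 6 fetal programme genes fell, 1 rose and 5 did not pass (7 and 1 adjusted over the list alone, set adjusted p = 1.08e-05, or 0.0152 with an estimated correlation), led by IGF2BP1 (-4.62) and LIN28B (-3.43), with IGF2BP3 (-0.69) also lower. LIN28B read 6.94 to 8.95 CPM at 1 DOA, above 4.07 to 5.28 at 90 DG, and 0 to 0.128 at 7 MOA. IGF2BP3 read 27.9 to 31.5 at 1 DOA, within the prenatal 27.1 to 52.2, and 8.60 to 19.2 at 7 MOA. 11 MHC class I genes rose and 2 did not pass (12 adjusted over the list alone, set adjusted p = 1.31e-06, or 0.0454 with an estimated correlation), led by PSME1 (1.21) and TAPBP (1.58). 13 interferon genes rose, 1 fell and 12 did not pass (14 and 1 adjusted over the list alone, set adjusted p = 1.08e-04, or 0.305 with an estimated correlation), including CMPK2 (3.78) besides HERC6. 8 cell cycle genes fell, 3 rose and 18 did not pass (set adjusted p = 0.00420, or 0.676 with an estimated correlation), with KIF20A (-0.71) and CENPE (-0.57) down. 5 globin and haem synthesis genes fell, 3 rose and 8 did not pass (6 and 3 adjusted over the list alone, set adjusted p = 0.0223, or 0.605 with an estimated correlation), with the embryonic zeta-globin HBZ (-1.96 ± 0.26, adjusted p = 8.05e-05, 55.7 ± 27.3 against 428 ± 492 CPM) down and ZBTB7A (0.86), a repressor of fetal globin, up, while the mu-globin HBM (0.19) did not pass. The glucocorticoid (3 up, 2 down, adjusted p = 0.411) and stress (1 up, 1 down, adjusted p = 0.0837) lists did not pass. The main cluster of the class differed between most ages, and cluster 20, 40.2% of the class at 1 DOA, came to 97.5% from 1 DOA replicate 1. Without the 60 DG libraries 992 genes passed. HERC6 stood at 5.34 and 5.30 without 47 DG replicate 2 or 7 MOA replicate 3. SLC2A1 stood at -7.86 without 1 DOA replicate 2. IGF2BP1 stood at -6.19 without 7 MOA replicate 3. CMPK2 stood at 2.23 and 2.22 without the 47 DG libraries or without 47 DG replicate 2. KIF20A lost its call without the 60 DG libraries (-0.57, adjusted p up to 0.0596). CENPE lost its call without the 60 DG libraries (-0.33, adjusted p up to 0.230). ZBTB7A lost its call without the 60 DG libraries (0.47, adjusted p up to 0.122). HBM turned to -0.65 without the 47 DG libraries or without 47 DG replicate 2.

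From 1 DOA to 7 MOA (3 libraries each) 1086 genes rose and 698 fell in erythroid-like cells. CA1 (5.25 ± 0.38, adjusted p = 7.44e-07, 2538 ± 759 against 66.8 ± 18.9 CPM), HERC6 (4.48 ± 0.76) and JAZF1 (3.55 ± 0.38), a zinc-finger protein, rose most. NPM3 (-1.86 ± 0.32), HMGA1 (-1.79 ± 0.29) and the chaperone HSPH1 (-1.62 ± 0.30) fell most. 10 globin and haem synthesis genes rose and 6 did not pass (11 adjusted over the list alone, set adjusted p = 1.31e-06, or 0.330 with an estimated correlation), among them UROS (1.57) and KLF3 (1.45), and HBM (1.96) rose, with HBZ (0.65) not passing. 7 fetal programme genes fell, 1 rose and 4 did not pass (set adjusted p = 1.31e-06, or 0.0122 with an estimated correlation), with LIN28B (0.0720 ± 0.0655 against 7.76 ± 1.05 CPM), IGF2BP1 (0.0293 ± 0.0508 against 3.50 ± 1.22 CPM) and IGF2BP3 (-1.09) lower. 11 interferon genes rose and 15 did not pass (set adjusted p = 1.08e-04, or 0.305 with an estimated correlation), such as IFI6 (2.41) and HERC6. 4 cell cycle genes rose and 25 did not pass (5 adjusted over the list alone, set adjusted p = 1.76e-05, or 0.505 with an estimated correlation), with CCNB2 (0.92) and KIF11 (0.78) up. The stress (5 up, 3 down, or 6 and 4 over the list alone, adjusted p = 0.121), MHC class I (0 up, 1 down, adjusted p = 0.758) and glucocorticoid (0 up, 2 down, adjusted p = 0.455) lists did not pass. With DESeq2 2800 genes passed, and without 1 DOA replicate 2 or 3 or 7 MOA replicate 3 only 611, 527 and 572. HERC6 stood at 3.21 without 7 MOA replicate 3. JAZF1 stood at 2.90 without 7 MOA replicate 3. HBM lost its call without 1 DOA replicate 3 (1.75, adjusted p up to 0.0508). IGF2BP1 stood at -9.54 without 7 MOA replicate 3. IFI6 lost its call with finer clusters (1.59, adjusted p up to 0.0806). CCNB2 lost its call without 1 DOA replicates 2 and 3 or 7 MOA replicates 2 and 3 (0.81 to 0.89, adjusted p up to 0.0909). KIF11 lost its call with no expression filter or without 1 DOA replicates 2 and 3 or 7 MOA replicates 2 and 3 (0.61 to 0.74, adjusted p up to 0.119).

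Between 60 and 90 DG (3 libraries each) 2846 genes rose and 1612 fell in erythroid-like cells, 63.8% of them upwards and 51.9% with RLE scaling. HBB in other cells moved with this comparison, as did the median genes per cell (329 to 385 at 60 DG, 938.5 to 1419 at 90 DG). RAVER2 (64.0 ± 10.5 against 0.282 ± 0.315 CPM) and UBALD2 (7.30 ± 0.42, adjusted p = 1.15e-08, 229 ± 12.8 against 1.46 ± 0.285 CPM) rose most. ADAMTS12 (-13.25 ± 3.35) and HENMT1 (-12.93 ± 2.84) fell most. No list passed its set test. 11 cell cycle genes rose and 18 did not pass (set adjusted p = 0.119), among them E2F1 (2.84) and TYMS (1.86). 5 interferon genes fell and 21 did not pass (set adjusted p = 0.202), such as IFIT1 (-2.43 ± 0.51, 78.8 ± 24.7 against 426 ± 36.3 CPM) and IFIT2 (-4.18). 4 globin and haem synthesis genes rose, 2 fell and 10 did not pass (set down at adjusted p = 0.917), with ZBTB7A (2.33) and the theta-globin HBQ1 (2.41) up, HBM (1.83) also up and HBZ (-0.07) not passing. 3 fetal programme genes rose, 1 fell and 8 did not pass (set adjusted p = 0.952), with HMGA1 (3.23) up, LIN28B (-1.03) down and IGF2BP3 (-0.46) not passing. The stress (6 up, 1 down, adjusted p = 0.519), glucocorticoid (1 up, 4 down, adjusted p = 0.114) and MHC class I (3 up, 0 down, adjusted p = 0.813) lists did not pass. RAVER2 stood at 8.71 without 60 DG replicate 1. ADAMTS12 lost its call without 90 DG replicate 2 (-16.99, adjusted p up to 0.0629) and stood at -13.84 and -12.56 without 60 DG replicates 1 and 3. HENMT1 stood at -12.32 without 60 DG replicate 3. IFIT1 lost its call at 500 genes per cell (-1.04, adjusted p up to 0.0505). IFIT2 lost its call with doublets removed by rate (-2.80, adjusted p up to 0.0636) and stood at -3.49 without 60 DG replicate 1. HBZ turned to 1.02 and 0.26 at 500 genes per cell or without 60 DG replicate 2. LIN28B lost its call without 60 DG replicate 3 (-0.91, adjusted p up to 0.0577). IGF2BP3 passed with DESeq2 (-0.65, adjusted p from 0.0277).

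Neutrophil-lineage-like cells (6 against 12 libraries) had 2723 genes that rose and 2053 that fell after birth of 10721. CLNK (8.14 ± 0.40, adjusted p = 1.30e-10, 59.9 ± 48.9 against 0.340 ± 0.575 CPM), an immunoreceptor adaptor at 100.1 CPM at 1 DOA and 19.6 at 7 MOA, ACSL6 (1.79 ± 0.14), an acyl-CoA synthetase, SSH2 (1.78 ± 0.23), a cofilin phosphatase, and MEIKIN (1.62 ± 0.17) rose most. BTG2 (-3.64 ± 0.38), RHOB (-3.44 ± 0.27, adjusted p = 1.56e-08, 99.4 ± 90.8 against 740.2 ± 302 CPM), HSPA6 (-3.41 ± 0.22) and ZFP36 (-3.31 ± 0.32), which destabilises cytokine mRNA, fell most. 16 stress genes fell and 2 did not pass (set adjusted p = 2.83e-15, or 0.0827 with an estimated correlation), such as IER2 (-1.88) and HSPH1 (-1.85). 11 neutrophil effector genes fell, 3 rose and 10 did not pass (set adjusted p = 9.97e-04, or 0.440 with an estimated correlation), the falls including TLR4 (-1.60) and CHI3L1 (-1.14). 13 interferon genes rose, 1 fell and 14 did not pass (16 and 1 adjusted over the list alone, set adjusted p = 0.00442, or 0.550 with an estimated correlation), led by USP18 (2.32) and HERC5 (2.15). 15 cell cycle genes rose and 14 did not pass (16 adjusted over the list alone, set adjusted p = 0.00466, or 0.605 with an estimated correlation), such as MCM2 (1.21) and MCM4 (1.06), replication licensing factors. 8 glucocorticoid genes fell, 4 rose and 3 did not pass (8 and 5 adjusted over the list alone, set adjusted p = 0.0524), with CXCR4 (-1.58), the marrow retention receptor, and PIK3IP1 (-2.47) down. 4 fetal programme genes fell, 1 rose and 5 did not pass (set adjusted p = 0.115), with IGF2BP2 (-2.16) and LIN28B (-2.64) down, GPC3 (2.04) up and IGF2BP3 (-0.35) not passing. At 1 DOA LIN28B read 1.71 to 3.69 CPM, within the prenatal 0 to 10.9, and IGF2BP2 28.1 to 38.4, near 25.8 to 38.5 at 90 DG, against 0.11 to 0.136 and 0.815 to 5.81 at 7 MOA. The MHC class I (3 up, 3 down, adjusted p = 0.828) list did not pass. The largest cluster of the class was 0 at 47 DG (70.9%), 6 at 60 DG (76.7%), 11 at 1 DOA (31.1%) and 2 at 7 MOA (36.3%). Without the 60 DG libraries 2848 genes passed. CLNK stood at 7.07 to 9.03 without the 60 DG libraries or without 47 DG replicate 2 or 75 DG replicate 2. HSPA6 stood at -4.005 and -2.83 without the 47 DG libraries or without the 60 DG libraries. TLR4 lost its call with finer clusters (-0.18, adjusted p up to 0.393). MCM2 stood at 0.59 without the 60 DG libraries. LIN28B stood at -2.02 without 60 DG replicate 3. IGF2BP3 passed without 7 MOA replicate 2 (-0.59, adjusted p from 0.0245).

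From 1 DOA to 7 MOA (3 libraries each) 2378 genes rose and 2239 fell in neutrophil-lineage-like cells, whose largest clusters were 11 at 1 DOA (31.1%) and 2 at 7 MOA (36.3%). PMAP-36 (6.12 ± 1.55), a porcine cathelicidin, CXCL8 (5.97 ± 0.80, adjusted p = 1.27e-04, 224 ± 89.7 against 3.57 ± 1.85 CPM), the neutrophil chemokine, and G0S2 (5.46 ± 0.84), an inhibitor of triglyceride lipase, rose most. KIT (-2.82 ± 0.40, adjusted p = 7.15e-05, 27.4 ± 9.83 against 194 ± 1.17 CPM), the stem cell factor receptor, TM7SF3 (-2.63 ± 0.29) and SDF2L1 (-2.53 ± 0.31) fell most. 24 interferon genes rose and 4 did not pass (25 adjusted over the list alone, set adjusted p = 2.71e-09, or 0.238 with an estimated correlation), led by IFI44L (2.88) and RSAD2 (5.54). 18 neutrophil effector genes rose, 1 fell and 5 did not pass (set adjusted p = 9.43e-09, or 0.178 with an estimated correlation), led by ADAM8 (2.34) and ARG2 (1.92), arginase 2. 13 stress genes rose, 1 fell and 4 did not pass (set adjusted p = 1.01e-05, or 0.308 with an estimated correlation), with IER2 (2.19) and ATF3 (3.72) up. 22 cell cycle genes fell and 7 did not pass (24 adjusted over the list alone, set adjusted p = 1.39e-04, or 0.505 with an estimated correlation), led by MCM2 (-0.87) and TYMS (-0.93). 9 MHC class I genes rose, 2 fell and 2 did not pass (set adjusted p = 0.0248, or 0.505 with an estimated correlation), with CALR (-2.42) down and PSMB9 (2.39) up. 6 fetal programme genes fell, 1 rose and 3 did not pass (set adjusted p = 0.00328, or 0.187 with an estimated correlation), led by IGF2BP2 (-3.41), with LIN28B (0.120 ± 0.0140 against 2.90 ± 1.05 CPM) and IGF2BP3 (-1.64) lower. The glucocorticoid (7 up, 3 down, adjusted p = 0.16) list did not pass. With RLE scaling 38.4% of the changed genes rose, against 51.5%. PMAP-36 stood at 4.77 without 7 MOA replicate 2. RSAD2 stood at 4.45 without 7 MOA replicate 3. IGF2BP2 stood at -4.12 without 7 MOA replicate 1.

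Between 60 and 90 DG (3 libraries each) 2290 genes rose and 1849 fell in neutrophil-lineage-like cells, held mainly in cluster 6 at 60 DG and cluster 0 at 90 DG. PMAP-36 (8.96 ± 2.21) and H1-10 (6.44 ± 0.40, adjusted p = 7.97e-10, 1167 ± 279 against 14.1 ± 4.80 CPM), a linker histone, rose most. ALAS2 (-3.90 ± 1.38, 37.4 ± 43.1 against 735 ± 268 CPM), the erythroid enzyme of haem synthesis, and ARG1 (-3.54 ± 1.28) fell most, while HBB took 6.59 points more of these cells' UMIs in the lowest 60 DG than in the highest 90 DG library. No list passed its set test. 18 cell cycle genes rose and 11 did not pass (set adjusted p = 0.0545), led by TYMS (2.54) and MCM2 (2.80). 9 neutrophil effector genes fell, 3 rose and 12 did not pass (set adjusted p = 0.283), with TLR4 (-1.59) down. 2 fetal programme genes rose, 1 fell and 7 did not pass (set adjusted p = 0.707), with HMGA1 (2.78) up, IGF2BP2 (-1.53) down and LIN28B (-0.27) and IGF2BP3 (0.19) not passing. The interferon (1 up, 6 down, adjusted p = 0.178), glucocorticoid (2 up, 6 down, adjusted p = 0.284), stress (5 up, 3 down, or 6 and 4 over the list alone, adjusted p = 0.631) and MHC class I (2 up, 2 down, adjusted p = 0.745) lists did not pass. PMAP-36 stood at 7.59 to 15.49 without 60 DG replicates 2 and 3 or 90 DG replicates 1 and 2. ALAS2 lost its call with no expression filter, at 100 cells per library, at 500 genes per cell or without 60 DG replicates 2 and 3 or 90 DG replicates 1, 2 and 3 (-4.94 to -3.42, adjusted p up to 0.150). ARG1 lost its call with no expression filter, at 100 cells per library, at 500 genes per cell or without 60 DG replicates 2 and 3 or 90 DG replicates 1, 2 and 3 (-3.85 to -2.61, adjusted p up to 0.169). MCM2 stood at 2.08 without 60 DG replicate 3. TLR4 lost its call with finer clusters (-0.50, adjusted p up to 0.365). LIN28B turned to 0.73 and 2.23 with finer clusters or without 60 DG replicate 3. IGF2BP3 turned to -0.08 without 90 DG replicate 2.

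For B-precursor-like cells the postnatal side was 1 DOA alone (3 libraries against 10), since 7 MOA held too few, and 1356 genes rose and 764 fell of 11453. SYNPR (3.18 ± 0.29, adjusted p = 1.68e-05, 152 ± 16.9 against 46.2 ± 43.4 CPM), TMEM160 (1.68 ± 0.26), TMEM63A (1.63 ± 0.20) and ANTKMT (1.58 ± 0.18) rose most. EGR1 (-5.59 ± 0.86, adjusted p = 0.00195, 1.10 ± 0.921 against 68.2 ± 63.3 CPM), an immediate early factor, TENM3 (-4.18 ± 0.79), RHOB (-3.90 ± 0.44) and RPGRIP1L (-2.92 ± 0.41) fell most. 11 B-cell development genes rose, 1 fell and 9 did not pass (13 and 2 adjusted over the list alone, set adjusted p = 1.18e-04, or 0.164 with an estimated correlation), led by CD38 (2.84) and IKZF3 (1.56), Aiolos. 9 stress genes fell and 9 did not pass (set adjusted p = 4.95e-05, or 0.238 with an estimated correlation), such as DNAJB1 (-1.47) and JUN (-1.95). 5 fetal programme genes fell and 6 did not pass (set adjusted p = 0.00107, or 0.161 with an estimated correlation), led by IGF2BP1 (-5.20) and IGF2BP2 (-2.40), with LIN28B (-1.19) also down and IGF2BP3 (-0.08) not passing. 3 V(D)J recombination genes fell, 1 rose and 10 did not pass (set adjusted p = 0.387), with the recombinase genes RAG2 (-1.57) and RAG1 (-1.10) down and DNTT (0.39), the transferase that adds untemplated nucleotides, not passing. The interferon (2 up, 4 down, adjusted p = 0.0934), glucocorticoid (3 up, 1 down, or 3 and 2 over the list alone, adjusted p = 0.283), cell cycle (1 up, 0 down, adjusted p = 0.633), MHC class I (1 up, 0 down, adjusted p = 0.825) and MHC class II (1 up, 1 down, or 1 and 2 over the list alone, adjusted p = 0.603) lists did not pass. Cluster 12 held 90.3% of the class at 47 DG and cluster 19 held 59.7% at 1 DOA. Without the 60 DG libraries 690 genes passed, and without 60 DG replicate 3 alone 3548. SYNPR stood at 1.68 without the 47 DG libraries. TMEM160 lost its call without the 60 DG libraries (0.51, adjusted p up to 0.256). ANTKMT stood at 0.69 without the 60 DG libraries. TENM3 stood at -3.30 without the 60 DG libraries. IKZF3 stood at 0.87 without the 47 DG libraries. JUN stood at -2.54 without the 60 DG libraries. IGF2BP3 turned to 0.01 to 0.12 without the 47 DG libraries, without the 60 DG libraries or without 60 DG replicate 3 or 90 DG replicate 2. RAG1 lost its call without the 60 DG libraries (-0.58, adjusted p up to 0.0517).

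Between 60 DG (3 libraries) and 90 DG (2 libraries) 2788 genes rose and 2087 fell in B-precursor-like cells, held mainly in cluster 12 (86.3%) and cluster 19 (55.3%). HBB took 3.74% to 7.17% of their UMIs at 60 DG and 0.480% to 1.07% at 90 DG, with medians of 1155.5 to 1259 and 1863 to 2028 genes per cell. BCL7C (77.1 ± 0.163 against 0 ± 0 CPM) and TMEM238 (54.4 ± 9.65 against 0 ± 0 CPM) rose from no UMI at 60 DG, and MARCHF11 (-6.87 ± 1.07, adjusted p = 5.62e-04) and TENM3 (-4.01 ± 0.90) fell most. 8 stress genes rose, 1 fell and 9 did not pass (9 and 1 adjusted over the list alone, set adjusted p = 0.0287, or 0.491 with an estimated correlation), led by IER5 (2.44) and JUN (2.78). 5 V(D)J recombination genes fell, 3 rose and 6 did not pass (set adjusted p = 0.268), with POLM (3.70) up and RAG1 (-1.89) and DNTT (-1.26) down. 13 cell cycle genes rose, 2 fell and 14 did not pass (set adjusted p = 0.111), such as PLK1 (3.23). The B-cell development (8 up, 4 down, adjusted p = 0.230), interferon (2 up, 8 down, adjusted p = 0.192), MHC class I (5 up, 2 down, adjusted p = 0.694), MHC class II (4 up, 0 down, adjusted p = 0.187) and glucocorticoid (2 up, 5 down, or 3 and 5 over the list alone, adjusted p = 0.531) lists did not pass. 3 fetal programme genes fell, 1 rose and 7 did not pass (4 and 1 adjusted over the list alone, set adjusted p = 0.187), with IGF2BP2 (-3.15) and IGF2BP3 (-1.09) down and LIN28B (-0.75) not passing. TENM3 stood at -2.83 without 60 DG replicate 3. DNTT lost its call without 60 DG replicate 3 (-1.22, adjusted p up to 0.0572). PLK1 stood at 4.18 and 2.60 without 60 DG replicates 1 and 3. LIN28B passed without 60 DG replicates 1 and 2 (-0.97 and -0.96, adjusted p from 0.0352).

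DP-thymocyte-like cells (6 against 9 libraries) carried DNTT, the terminal transferase, at 12.7, 48.4 and 108 CPM at 60, 75 and 90 DG and at 309.8 and 505.5 at 1 DOA and 7 MOA, and 1873 genes rose and 2011 fell of 11314. DNTT (3.30 ± 0.10, adjusted p = 6.25e-13), ZBBX (2.37 ± 0.17), DEGS2 (1.36 ± 0.14) and TRPS1 (1.31 ± 0.11) rose most. LIN28B (-6.60 ± 0.23, adjusted p = 4.53e-12, 0.882 ± 0.740 against 61.5 ± 32.4 CPM), RHOB (-5.31 ± 0.46), ID1 (-4.95 ± 0.38) and BAG3 (-4.27 ± 0.35) fell most. 7 fetal programme genes fell, 1 rose and 2 did not pass (set adjusted p = 1.61e-05, or 0.0321 with an estimated correlation), with PLAG1 (-2.77), IGF2BP2 (-4.59) and IGF2BP3 (-1.05) also down. At 1 DOA IGF2BP3 read 167 to 247 CPM, not below the prenatal 109.4 to 240.1, and 16.4 to 47.2 at 7 MOA. IGF2BP2 read 69.8 to 117 at 1 DOA, overlapping 90.9 to 142 at 90 DG, and 0.519 to 1.49 at 7 MOA. 16 stress genes fell and 1 did not pass (set adjusted p = 7.14e-12, or 0.178 with an estimated correlation), such as JUNB (-2.87) and KLF6 (-1.46). 8 TCR signal response genes fell, 1 rose and 7 did not pass (10 and 1 adjusted over the list alone, set adjusted p = 0.00375, or 0.421 with an estimated correlation), led by CD69 (-1.41) and IKZF2 (-0.55). 4 V(D)J recombination genes rose, 3 fell and 6 did not pass (5 and 3 adjusted over the list alone, set adjusted p = 0.253), with HMGB2 (-0.86) down and RAG1 (0.26) not passing. The glucocorticoid (5 up, 4 down, adjusted p = 0.875), interferon (5 up, 4 down, adjusted p = 0.434), cell cycle (3 up, 1 down, or 2 and 0 over the list alone, adjusted p = 0.841) and MHC class I (1 up, 2 down, adjusted p = 0.628) lists did not pass. Cluster 0 held 75.1% of the class at 60 DG, cluster 3, led by the heat shock genes DNAJB1, HSPA6 and HSPH1, 50.2% at 90 DG, cluster 1 82.0% at 1 DOA and cluster 6 54.7% at 7 MOA. IKZF2 lost its call with finer clusters (-0.23, adjusted p up to 0.0925). RAG1 passed with DESeq2 or without 90 DG replicate 3 or 7 MOA replicate 2 (0.26 to 0.34, adjusted p from 0.00571).

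From 1 DOA to 7 MOA (3 libraries each) 909 genes rose and 763 fell in DP-thymocyte-like cells. RHOB (4.71 ± 0.67, adjusted p = 0.00285, 149 ± 121 against 5.72 ± 3.35 CPM), AVP (3.54 ± 0.71), the vasopressin precursor, and FOS (3.09 ± 0.82) rose most. IGF2BP2 (-6.97 ± 0.37, adjusted p = 2.33e-08, 0.875 ± 0.533 against 96.8 ± 24.2 CPM), NHS (-5.63 ± 0.64) and GABRB2 (-3.89 ± 0.98) fell most. 5 fetal programme genes fell and 5 did not pass (set adjusted p = 4.05e-05, or 0.0378 with an estimated correlation), with PLAG1 (-3.31) and IGF2BP3 (-2.96) following IGF2BP2 and LIN28B (0.233 ± 0.318 against 1.53 ± 0.0766 CPM) also lower. 8 stress genes rose and 9 did not pass (11 adjusted over the list alone, set adjusted p = 1.31e-06, or 0.333 with an estimated correlation), led by KLF6 (1.29) and JUN (1.82). 2 V(D)J recombination genes rose, 1 fell and 10 did not pass (3 and 4 adjusted over the list alone, set down at adjusted p = 0.952), with DNTT (0.71) up and RAG1 (0.19) not passing. The TCR signal response (3 up, 3 down, adjusted p = 0.564), interferon (4 up, 0 down, or 5 and 0 over the list alone, adjusted p = 0.134), MHC class I (4 up, 1 down, or 5 and 1 over the list alone, adjusted p = 0.351), cell cycle (0 up, 1 down, or 0 and 0 over the list alone, adjusted p = 0.813) and glucocorticoid (1 up, 1 down, adjusted p = 0.813) lists did not pass. Without 1 DOA replicate 2 or 3 or 7 MOA replicate 1 or 2, 356, 548, 741 and 577 genes passed. RHOB stood at 3.85 without 7 MOA replicate 1. AVP lost its call without 1 DOA replicate 2 (3.20, adjusted p up to 0.0630) and stood at 4.99 and 2.77 without 1 DOA replicate 1 or 7 MOA replicate 1. FOS lost its call with no expression filter or without 1 DOA replicates 1 and 2 or 7 MOA replicate 1 (2.00 to 3.06, adjusted p up to 0.133) and stood at 4.05 without 1 DOA replicate 3. NHS stood at -6.67 and -4.89 without 7 MOA replicates 2 and 3. GABRB2 lost its call without 1 DOA replicates 2 and 3 or 7 MOA replicates 1 and 2 (-3.89 to -3.54, adjusted p up to 0.0985) and stood at -5.50 without 7 MOA replicate 3. LIN28B lost its call without 7 MOA replicate 3 (-2.25, adjusted p up to 0.0606) and stood at -3.96 without 7 MOA replicate 1.

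Between 60 and 90 DG (3 libraries each) 526 genes rose and 637 fell in DP-thymocyte-like cells. LONRF2 (8.62 ± 2.06) and DNTT (3.11 ± 0.18, adjusted p = 2.63e-08) rose most. CHD7 (-4.71 ± 0.47, adjusted p = 1.07e-04, 4.31 ± 3.09 against 123 ± 29.7 CPM), a chromatin remodeller, and SOX18 (-3.79 ± 0.59) fell most. 4 fetal programme genes fell, 1 rose and 5 did not pass (5 and 1 adjusted over the list alone, set adjusted p = 0.0104, or 0.178 with an estimated correlation), with LIN28B (-1.73) and IGF2BP2 (-1.81) down, BEX1 (1.87) up and IGF2BP3 (-0.58) not passing. 2 stress genes rose and 15 did not pass (4 adjusted over the list alone, set adjusted p = 0.00219, or 0.512 with an estimated correlation), FOSB (2.27) and HSPA8 (1.23). 3 V(D)J recombination genes rose, 1 fell and 9 did not pass (3 and 2 adjusted over the list alone, set adjusted p = 0.283), with DCLRE1C (0.69), Artemis, up, and RAG1 (0.29) not passing. The TCR signal response (3 up, 3 down, or 5 and 4 over the list alone, adjusted p = 0.917), glucocorticoid (2 up, 1 down, adjusted p = 0.606), interferon (2 up, 0 down, or 3 and 0 over the list alone, adjusted p = 0.629), MHC class I (2 up, 0 down, or 3 and 1 over the list alone, adjusted p = 0.0960) and cell cycle (1 up, 0 down, or 0 and 0 over the list alone, adjusted p = 0.0837) lists did not pass. Without 60 DG replicate 1 or 2 or 90 DG replicate 1 or 2, 584, 554, 457 and 527 genes passed. LONRF2 lost its call without 60 DG replicates 1, 2 and 3 or 90 DG replicate 2 (8.03 to 9.78, adjusted p up to 0.10) and stood at 9.22 without 90 DG replicate 1. HSPA8 lost its call without 60 DG replicates 1 and 2 or 90 DG replicates 1 and 2 (0.98 to 1.17, adjusted p up to 0.997) and turned to -0.00300 with finer clusters. DCLRE1C lost its call without 60 DG replicate 1 (0.64, adjusted p up to 0.0631).

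**Figure D4:**
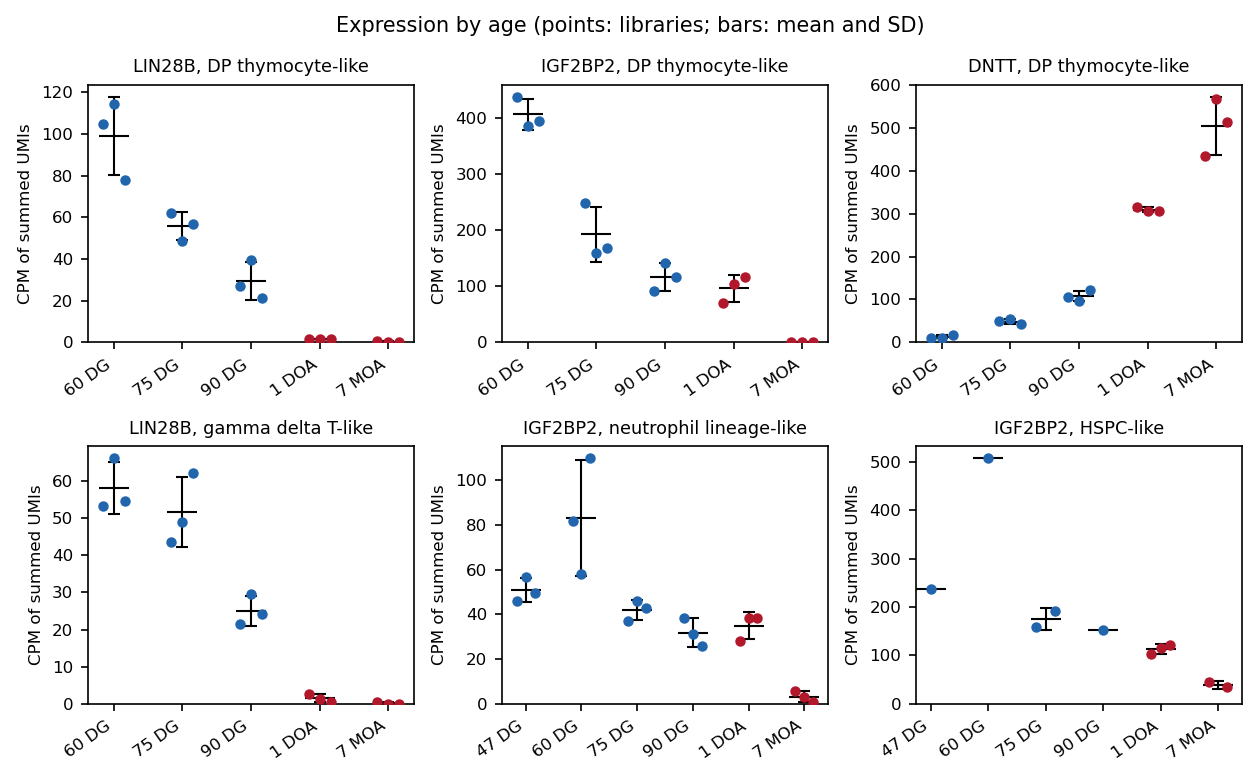
CPM of summed UMIs per library (vertical axes) by age (horizontal axes) for LIN28B, IGF2BP2 and DNTT in DP-thymocyte-like, LIN28B in gamma-delta T-like and IGF2BP2 in neutrophil-lineage-like and HSPC-like cells, with points for libraries, blue before and red after birth, and bars for mean and SD where an age has more than 1 library. DNTT of DP-thymocyte-like cells reads 12.7 CPM at 60 DG and 505.5 at 7 MOA, and LIN28B 99.2 and 0.233.

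Gamma-delta T-like cells (6 against 9 libraries) had 1341 genes that rose and 1324 that fell after birth of 10750. DIPK1A (1.44 ± 0.18), PAG1 (1.07 ± 0.12, adjusted p = 8.97e-06, 274 ± 47.8 against 135 ± 33.2 CPM), a Csk-binding adaptor, ATP8A1 (1.03 ± 0.12), a flippase, and HDAC9 (1.03 ± 0.11) rose most. HSPA6 (-3.83 ± 0.42, adjusted p = 1.40e-04, 64.0 ± 52.5 against 863 ± 464 CPM), RHOB (-3.56 ± 0.25), IGF2BP2 (-3.52 ± 0.20) and BAG3 (-3.49 ± 0.39) fell most. 7 fetal programme genes fell, 1 rose and 2 did not pass (set adjusted p = 1.39e-06, or 0.0122 with an estimated correlation), led by LIN28B (-6.37) and IGF2BP2, with IGF2BP3 (-0.90) lower. At 1 DOA IGF2BP3 read 199.8 to 245 CPM, not below the prenatal 110.6 to 206, and 13.1 to 58.7 at 7 MOA. 13 stress genes fell and 5 did not pass (15 adjusted over the list alone, set adjusted p = 1.32e-10, or 0.178 with an estimated correlation), such as IER2 (-0.78) and ATF3 (-1.71). 10 cell cycle genes fell and 19 did not pass (set adjusted p = 0.0874), such as KIF20A (-0.74) and CCNA2 (-0.58). 3 gamma-delta effector genes fell and 12 did not pass (set adjusted p = 0.0507), among them ZBTB16 (-2.42), PLZF. The glucocorticoid (4 up, 2 down, adjusted p = 0.763), interferon (1 up, 3 down, adjusted p = 0.363), MHC class I (1 up, 1 down, adjusted p = 0.828) and TCR signal response (1 up, 0 down, adjusted p = 0.745) lists did not pass. Cluster 23 held 58.7% to 94.2% of the class except at 75 DG, where cluster 22 held 51.6%. LIN28B stood at -7.16 without 7 MOA replicate 1. IGF2BP3 lost its call with no expression filter, at 100 cells per library or without 60 DG replicates 1, 2 and 3, 75 DG replicates 1 and 3, 90 DG replicates 1, 2 and 3, 1 DOA replicates 1, 2 and 3 or 7 MOA replicate 1 (-0.95 to -0.79, adjusted p up to 0.0974). KIF20A lost its call with finer clusters (-0.17, adjusted p up to 0.234). CCNA2 lost its call with finer clusters (-0.17, adjusted p up to 0.231). ZBTB16 lost its call at 100 cells per library or without 90 DG replicate 1 or 7 MOA replicates 2 and 3 (-2.48 to -0.31, adjusted p up to 0.598).

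From 1 DOA to 7 MOA (3 libraries each) 113 genes rose and 90 fell in gamma-delta T-like cells. RHOB (3.22 ± 0.38, adjusted p = 0.00147, 99.1 ± 42.5 against 10.7 ± 4.04 CPM), RBM3 (1.30 ± 0.16), a cold-induced RNA-binding protein, and GYPC (1.25 ± 0.20), glycophorin C, rose most. IGF2BP2 (-5.49 ± 0.35, adjusted p = 3.31e-08, 1.42 ± 1.18 against 59.7 ± 7.37 CPM), S100A10 (-2.95 ± 0.28) and IGF2BP3 (-2.80 ± 0.44) fell most. 5 fetal programme genes fell and 5 did not pass (7 and 2 adjusted over the list alone, set adjusted p = 3.67e-08, or 0.0122 with an estimated correlation), with PLAG1 (-3.37) and LIN28B (0.147 ± 0.255 against 1.55 ± 1.08 CPM) lower. 2 gamma-delta effector genes fell and 13 did not pass (6 adjusted over the list alone, set adjusted p = 1.82e-05, or 0.252 with an estimated correlation), CXCR6 (-4.09) and IL23R (-3.45), receptors of tissue-resident and type 17 cells. 2 glucocorticoid genes fell and 12 did not pass (3 adjusted over the list alone, set adjusted p = 0.00829, or 0.371 with an estimated correlation), DDIT4 (-1.26) and FKBP5 (-1.33). 1 stress gene rose and 17 did not pass (6 adjusted over the list alone, set adjusted p = 0.00101, or 0.476 with an estimated correlation), BTG2 (0.62). 1 interferon gene rose and 23 did not pass (2 adjusted over the list alone, set adjusted p = 0.0137, or 0.557 with an estimated correlation), IRF7 (1.07). The MHC class I (2 up, 0 down, adjusted p = 0.250), cell cycle (0 up, 0 down, adjusted p = 0.828) and TCR signal response (0 up, 1 down, adjusted p = 0.460) lists did not pass. The count was 362 with DESeq2, 341 with no expression filter, 487 with finer clusters, 98, 58 and 78 without 1 DOA replicate 1, 2 or 3, and 77, 72 and 780 without 7 MOA replicate 1, 2 or 3. IGF2BP3 lost its call without 7 MOA replicate 1 (-2.61, adjusted p up to 0.0539) and stood at -3.72 without 7 MOA replicate 2. LIN28B lost its call with doublets removed by rate or without 1 DOA replicates 1 and 2 or 7 MOA replicates 2 and 3 (-3.66 to -2.62, adjusted p up to 0.208) and stood at -5.16 without 7 MOA replicate 1. CXCR6 stood at -5.54 without 7 MOA replicate 3. IL23R lost its call with no expression filter or without 1 DOA replicates 1, 2 and 3 or 7 MOA replicates 1 and 2 (-3.57 to -2.88, adjusted p up to 0.147) and stood at -4.63 without 7 MOA replicate 3. BTG2 lost its call without 1 DOA replicates 2 and 3 or 7 MOA replicates 1 and 2 (0.57 to 0.69, adjusted p up to 0.149). IRF7 lost its call with finer clusters, with doublets removed by rate or without 1 DOA replicates 1, 2 and 3 or 7 MOA replicate 2 (0.83 to 1.18, adjusted p up to 0.181).

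Between 60 and 90 DG (3 libraries each) 1054 genes rose and 1235 fell in gamma-delta T-like cells. IL17F (0.365 ± 0.378 against 68.2 ± 58.8 CPM), the cytokine, and AVP (-7.31 ± 0.89, adjusted p = 2.77e-04, 23.5 ± 14.1 against 3991 ± 2143 CPM) fell most. SLC24A3 (2.65 ± 0.49) and FADS3 (2.63 ± 0.46), a fatty acid desaturase, rose most. At 75 DG, IL17F stood at 2.92 CPM, and IL23R at 6.26, after 83.8 at 60 DG. 11 gamma-delta effector genes fell and 4 did not pass (set adjusted p = 9.43e-09, or 0.166 with an estimated correlation), such as MAF (-2.38) and NKG7 (-2.62). 12 interferon genes fell and 12 did not pass (13 adjusted over the list alone, set adjusted p = 3.01e-06, or 0.333 with an estimated correlation), led by BST2 (-2.19) and IRF7 (-2.003). 6 MHC class I genes fell and 7 did not pass (set adjusted p = 0.00709, or 0.178 with an estimated correlation), with TAPBP (-0.94) and PSME2 (-0.67) down. 17 cell cycle genes rose and 12 did not pass (24 adjusted over the list alone, set adjusted p = 1.04e-07, or 0.352 with an estimated correlation), such as TPX2 (1.19) and AURKB (0.96). 4 fetal programme genes fell, 2 rose and 4 did not pass (set adjusted p = 0.250), with IGF2BP1 (-3.69) and LIN28B (-1.19) down and IGF2BP3 (-0.10) not passing. The glucocorticoid (2 up, 4 down, adjusted p = 0.0618), stress (0 up, 3 down, adjusted p = 0.291) and TCR signal response (1 up, 2 down, or 0 and 2 over the list alone, adjusted p = 0.744) lists did not pass. Without 60 DG replicate 1, 1194 genes passed. With finer clusters AVP stood at -5.21, MAF at -1.62, NKG7 at -1.28, BST2 at -1.16, FADS3 at 1.36, SLC24A3 at 1.98, TPX2 at 2.02 and AURKB at 1.76. SLC24A3 stood at 2.03 without 60 DG replicate 1. FADS3 stood at 3.96 without 60 DG replicate 3. PSME2 lost its call with finer clusters (-0.09, adjusted p up to 0.656). IGF2BP1 stood at -3.06 and -5.25 without 90 DG replicates 1 and 2. IGF2BP3 turned to 0.16 and 0.03 without 60 DG replicate 2 or 90 DG replicate 1. Lists whose median, mean and set test differ in sign, of which none passed, were the glucocorticoid and stem cell lists in HSPC-like cells after birth, MHC class I in erythroid-like cells from 1 DOA to 7 MOA, interferon and globin in erythroid-like, MHC class I in neutrophil-lineage-like, glucocorticoid in B-precursor-like and interferon, glucocorticoid and TCR in DP-thymocyte-like cells from 60 to 90 DG, V(D)J in B-precursor-like and glucocorticoid in gamma-delta T-like cells after birth, and TCR in gamma-delta T-like cells from 1 DOA to 7 MOA.

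**Figure D5:**
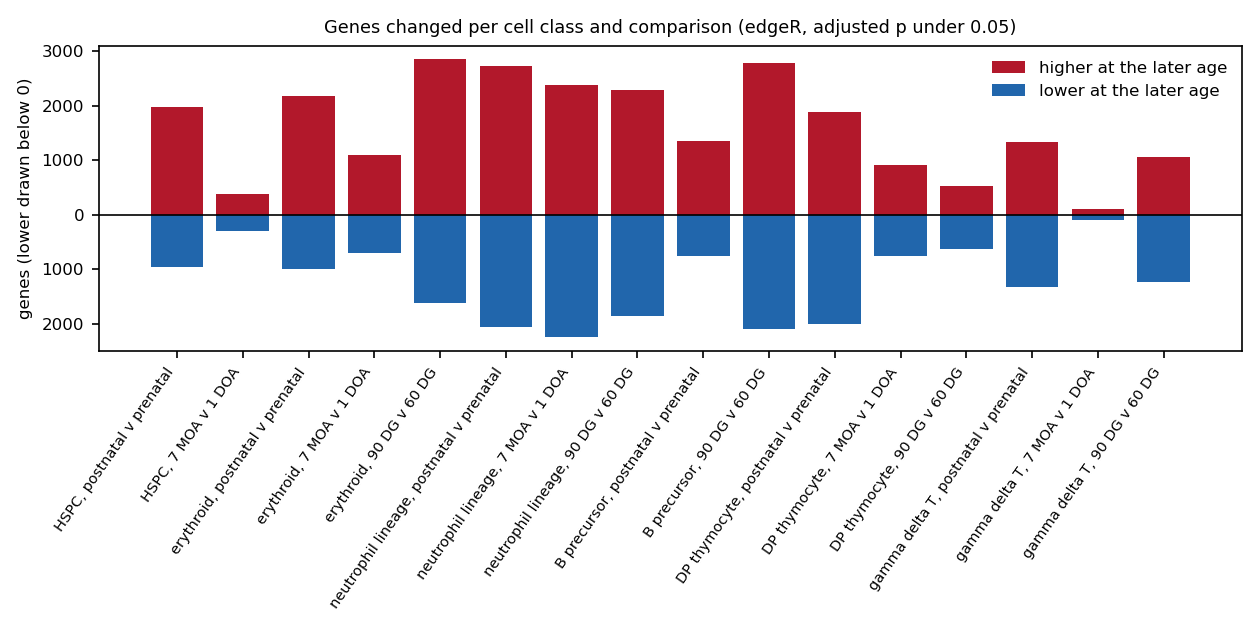
Numbers of genes higher (red, above 0) and lower (blue, below 0) at the later age for each cell class and comparison, at an adjusted p under 0.05 in edgeR. The bars for 7 MOA against 1 DOA stand at 2378 up and 2239 down for neutrophil-lineage-like and at 113 up and 90 down for gamma-delta T-like cells.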

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

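Tests of gene span and of a shift common to the marrow classes, and the DNTT comparison, were chosen after the results were seen, as were the limits for genes that move in opposite directions in the tissues (named genes at 1 CPM or more with an absolute log2 fold change over 1).

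In 60 DG marrow, replicate 3 held 1305 cells that resemble DP thymocytes, 21.1% of its cells. Of these, at most 1.61% share barcodes with any single thymus library and 10.1% with any of the 15, against up to 2.43% and 11.6% of the other cells. RAG1 in neutrophil-lineage-like cells of that library reached 0.649% of its level in them (7.75 against 1195 CPM). The shared barcodes argue against index hopping and the RAG1 level against free RNA. Their profile correlates with DP cells of 60 DG thymus at a Spearman rho of 0.903 and with 1 DOA at 0.905, too close to name an age. DNTT at 11.0 CPM, here of cells pooled per age without TMM, lies beside 11.99 in 60 DG thymus and below 47.3, 97.8, 342 and 516 at the later ages. Thymus tissue of the same age mixed in during dissection could explain this and cannot be told apart here from T-lineage cells in that marrow.

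In marrow, 60 and 90 DG libraries differ widely in each class tested. Fold changes follow gene span (Spearman rho -0.443 in B-precursor-like, -0.337 in erythroid-like and -0.224 in neutrophil-lineage-like cells), but as strongly elsewhere (-0.464 in DP-like cells from 1 DOA to 7 MOA, 0.393 in gamma-delta T-like cells after birth). Of the B-precursor-like genes changed over 2-fold, 70.1% stayed so without that trend, which argues against gene length as the whole cause but leaves it open for a part. 0 genes were lost in all 3 classes, the first criterion set for a library-wide loss, which misses partial losses. Each 60 DG library had at least 6.59 points more HBB in neutrophil-lineage-like cells than each 90 DG library, so free haemoglobin RNA is consistent with part of the pattern, for globin and other erythroid genes. Fold changes of class pairs correlate at 0.667, 0.668 and 0.701, against 0.384 to 0.485 after birth and 0.239 from 1 DOA to 7 MOA, but a shared effect of age gives this too, so a library-wide shift and an effect of age cannot be told apart.

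Immediate early and heat shock genes were lower after birth in 9 of 9 thymus classes (mean log2 difference -1.83 in DP, -1.28 in SP, -0.905 in gamma-delta T and -0.762 in double-negative cells). Handling that reaches every cell type could explain this, as neutrophils share it (-1.42). Cluster 3 does not carry it alone, as 71.3% of the DP difference remained without it. This cluster held 0.112% (1 DOA) to 23.6% (90 DG) of a library's cells. An effect of age in each cell type stays open.

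Erythroid-like cells of liver replicate 1 lie far from the others (79.0% against 62.3% to 64.1%, gap over range 0.889), and chance alone marks about 1 in 20 groups. In marrow barcodes under 200 genes at 60 DG, which no comparison uses, HBB took 54.2% of UMIs on average. Some genes moved one way in every library of a marrow class and the other way in thymus, a difference not itself tested. From 1 DOA to 7 MOA these were DDIT4 (2.82 in neutrophil-lineage-like, -1.26 in gamma-delta T-like cells) and JAZF1 (3.55 in erythroid-like, -1.55 in DP-like cells), and after birth CD38 (2.84 in B-precursor-like, -1.25 in DP-like cells). From 60 to 90 DG, gamma-delta T-like cells opposed erythroid-like cells in ARID3A (-1.05, 1.27), neutrophil-lineage-like cells in CMPK2 (-2.36, 2.55) and NKG7 (-2.62, 1.32), and B-precursor-like cells in AVP (-7.31, 2.87), IRF7 (-2.003, 2.62), NFKBIA (-1.55, 1.84), SLC24A3 (2.65, -1.48) and ST3GAL6 (2.61, -1.02). DP-like cells opposed B-precursor-like cells in DNTT (3.11, -1.26) and, in SGK1 (1.52), neutrophil-lineage-like (-2.25), erythroid-like (-1.25) and B-precursor-like cells (-1.81).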

How the results depend on the processing

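Doublets by rate, no 60 DG libraries, low-gene barcodes as erythroid and thymocyte-like cells left out were run after the results were seen, and the cause of a change below was not tested beyond the smaller number of libraries. Of 553 named-gene results, 550 kept direction and side of the threshold with RLE factors or doublets kept, 531 with no filter and 545 with 500 genes per cell, where 2 turned, 1 of which had passed. With DESeq2 517 of 549 did, with doublets by rate 532 of 548, at 100 cells per library 424 of 437, where 2 turned, both of which had passed, and with finer clusters 499 of 551, where 12 turned, 8 of which had passed. Without 47 DG 133 of 141 did, where 2 that had not passed turned, and without 60 DG only 108 of 141, where 4 turned, 3 of which had passed. Without 1 library 4431 of 4766 did, where 11 turned, 3 of which had passed. In simulated data, 13 of 100 changes of 2-fold were found in B-precursor-like cells from 60 to 90 DG, so small changes there can go unseen, and HSPC-like cells numbered 45 to 236 per age. Gene set calls went from 54 to 7 with an estimated correlation (56 with RLE factors), and no list that had passed turned. Replicate numbers do not pair the libraries (mean correlation -0.0323 to 0.0153), and with the number as a replicate block 56 sets passed, 526 of 553 named-gene results were the same, gamma-delta T-like cells had 133 genes from 1 DOA to 7 MOA, and the thymus monocyte-like difference was 1.39 points (adjusted p = 0.066).

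Counts of changed genes stayed within 1.5 times in 122 of 129 planned and 16 of 20 added fits and in 118 of 138 without 1 library. After birth HSPC-like cells had 1009 with DESeq2 and 1226 without 60 DG (1235 to 3411 over libraries left out), erythroid-like 992, neutrophil-lineage-like 2848 and B-precursor-like cells 690 without 60 DG (1688 to 3548). From 1 DOA to 7 MOA the counts were 163 with DESeq2 in HSPC-like cells, 2800 in erythroid-like (527 to 2497), 356 to 2093 in DP-like, and 362 with DESeq2, 341 unfiltered and 487 with finer clusters in gamma-delta T-like cells (58 to 780). From 60 to 90 DG they ranged from 457 to 1333 in DP-like and 1194 to 2251 in gamma-delta T-like cells.

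Share differences in points, with the range over libraries left out, were as follows. In marrow, B-precursor-like cells passed at -6.21 with finer clusters, -16.3 of non-erythroid cells, -7.63 without 47 DG and -6.71 without thymocyte-like cells (-7.61 to -5.74), neutrophil-lineage-like at 22.4, 23.8 and 37.1 in the first 3 settings (22.3 to 30.1) and erythroid-like at -31.2 without 47 DG. The sign turned in DP-like cells (0.0583 without 60 DG, -1.88 to 0.0361), HSPC-like (-0.436 of non-erythroid), mature B or plasma-like (-2.68 of non-erythroid, -0.385 without 60 DG, -0.302 to 0.385), mesenchymal (-0.0520 with doublets by rate, -0.342 to 0.343) and monocyte-like cells (1.02 with finer clusters, 3.31 without 47 DG, -1.26 to 0.845). In thymus it turned with finer clusters in double-negative-like (-0.180) and gamma-delta T-like cells (-2.06) and in HSPC or double-negative-like cells (-0.442 to 0.116), and monocyte-like cells missed the threshold at 500 genes (0.692, with 1.26 to 1.74 over libraries). Over all classes, 314 of 348 library removals and 146 of 165 other settings changed neither sign nor call of a share difference. Liver shares moved under 1 SD in all 40 library removals and in 31 of 40 other settings.

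Among genes of the text, HBM in erythroid-like cells after birth turned to -0.65 without 47 DG (-0.65 to 0.33 over libraries) and HBZ from 60 to 90 DG to 1.02 at 500 genes (-0.33 to 0.26). LIN28B in neutrophil-lineage-like cells from 60 to 90 DG turned to 0.73 with finer clusters (-0.71 to 2.23), and HSPA8 in DP-like cells to -0.003. IGF2BP3 turned in B-precursor-like cells after birth to 0.02 without 47 DG and 0.12 without 60 DG (-0.13 to 0.038), and from 60 to 90 DG ranged from -0.076 to 0.58 in neutrophil-lineage-like and -0.28 to 0.16 in gamma-delta T-like cells. Of these only HSPA8 had passed.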

Other observations

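Marrow stroma differed between ages without a single direction. Mesenchymal cells, which hold up the niche, were 2.30% of kept cells at 47 DG, 0% at 90 DG, 1.64% at 1 DOA and 0.0142% at 7 MOA (n = 3 libraries each, from different bones before and after birth). Endothelial cells were 0.985%, 0.211%, 1.46% and 0.0733%, and bone-resorbing osteoclast-like cells 0.658%, 0.0101%, 0.529% and 0.00743% at these ages. At 1 DOA single libraries spread widely, from 0.417% to 2.72% endothelial and 0.157% to 1.24% osteoclast-like cells. Mast-cell-like cells were 0.0509% to 0.165% before birth, 0.774% at 1 DOA and 0.521% at 7 MOA, and like osteoclast-like cells they stayed under the 1% set for testing. In thymus, a cluster with HSPC and double-negative markers was 0.405% at 60 DG and 3.75% at 90 DG.

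The 10 splits of 3 against 3 libraries and the 60 splits drawn per postnatal comparison were fixed before the results were seen. Other splits of the postnatal and prenatal libraries gave fewer changed genes than the real split in HSPC-like (2920, highest other 2048), erythroid-like (3170, 1637), neutrophil-lineage-like (4776, 55), DP-like (3884, 1178) and gamma-delta T-like cells (2665, 1146), 1 of 60 splits each. The other splits mix libraries of different ages within a group, which widens its spread. They therefore cannot tell birth from any other difference between ages, bones or sampling. In HSPC-like cells 7 of the other splits gave over 1000 genes. For B-precursor-like cells 2 of 60 splits gave as many as the real 2120, and 1 split gave 5032, which points to a structure of the samples that was not examined further. With 3 against 3 libraries the 10 splits are too few for a share under 0.05, and the real one alone (1) reached its count. The counts, with the highest other, were 1784 (1) and 4458 (0) in erythroid-like, 4617 (0) and 4139 (1460) in neutrophil-lineage-like, 1672 (3) and 1163 (1) in DP-like and 203 (1) and 2289 (1) in gamma-delta T-like cells, from 1 DOA to 7 MOA and from 60 to 90 DG.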
